A study of Mus musculus with 8 samples.

How the data were processed

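RNA from primary mouse hepatic stellate cells was measured on 8 Affymetrix arrays, 2 in each of 4 groups named by the labels. Quiescent cells came from healthy BALB/c livers and were taken at 0 hours, without seeding. Cultured cells were the same kind of cell after 10 days on plastic. In vivo activated cells were taken without seeding from mice given carbon tetrachloride (CCl4) for 2 weeks or for 4 weeks. Per the labels' protocols, RNA was isolated with a column kit, preamplified with the Pico Ovation WTA V2 system and labelled with biotin by terminal transferase. A treatment protocol shared by all 8 samples names valproic acid at 2.5 mM after seeding, while no sample title or treatment label names it and 3 of the 4 groups were never seeded. Whether the cultured cells received it is not settled by the sources used here.

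The authors deposited log2 expression values, normalized with RMA in Affymetrix Expression Console per the submitters' processing notes, with versions not given in the sources used here. RMA corrects background, quantile normalizes the arrays together and summarises probes, so each value is relative to the other arrays and a change shared by most genes would not be seen. Medians over the 41345 probe sets ran from 4.63 to 4.72 log2 units on the 8 arrays, and the values were used as deposited. No detection calls were used. As a guide to background, the 1390 olfactory and vomeronasal receptor genes had a median of 3.22 and a 95th percentile of 4.76 log2 units, a guide chosen after the data were examined. For arrays, the number of replicates limits the precision.

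The platform annotation gave 1 gene symbol to 23521 probe sets and several to 1814, and 16010 probe sets were not named here. Symbols were checked through gene IDs against a RefSeq gene table of assembly GRCm38.p6, in which 193 IDs had no row and 0 symbols changed. The build behind the array design is not given in the sources used here, so no coordinates are printed. Only probe sets with 1 symbol were named. For the 1082 genes with several probe sets, the one with the highest mean over all arrays was used, which left 22180 genes. Probe sets of the same gene were called in opposite directions for 1 gene, and for 0 of the 22 named genes that had several. However, a dimmer probe set of Ccn2, Ch25h, Serpinb9b and Socs3 was not past the threshold for a change printed in the results.

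Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with neither trend nor robust option, in a single fit of all 8 arrays with 4 groups. The fit had 4 residual degrees of freedom and gained 4.75 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 22180 genes of each comparison, and a gene was called at an adjusted p under 0.05 with no fold threshold. Each test was two-sided. The 5 comparisons were culture against quiescent, each CCl4 time against quiescent, 4-week against 2-week CCl4, and culture against the mean of both CCl4 times. Changes are given as log2 fold change ± standard error (SE), with 2 arrays per group, 4 in the pooled CCl4 groups. The labels do not say that the arrays of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so no such test was used.

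There were 30 gene lists, fixed before the data were examined. They covered YAP/TAZ target genes, Hippo pathway components, quiescent and activated stellate cell markers, collagens, collagen processing, actin and contractility, matrix metalloproteinases, TGF-beta signalling, retinoid and lipid metabolism, cholesterol biosynthesis, proliferation, immediate early genes, cytokines, interferon response, oxidative phosphorylation, glycolysis, unfolded protein response, integrins and hedgehog signalling. Others held markers of hepatocytes, macrophages, monocytes and neutrophils, sinusoidal endothelial cells, lymphocytes, cholangiocytes, portal fibroblasts and vascular smooth muscle, or sex-linked genes. The 29 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, adjusted over the 145 list tests. Of these, 89 were past the threshold, and 0 of the 89 were past it with an estimated correlation, which rests on 4 residual degrees of freedom. The adjusted p with an estimated correlation therefore stands beside each list call. Counts of members are given over all genes and adjusted over the list alone. Some lists share members: 12 of 23 activated markers, 11 of 26 actin genes and 10 of 17 smooth muscle markers also stand in another list.

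Genes were named by a rule fixed at the same time. It took 16 genes in every comparison, the 10 largest rises and 10 largest falls past the threshold with the arrays of both groups apart (5 and 5 for 4-week against 2-week CCl4), up to 4 members of each list with the smallest p, and members that went against their list. Predicted genes, small RNAs and immune receptor segments were not named under the second part. Chance values shared through the quiescent arrays were estimated from 100 simulations of unchanged groups against the same controls.

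The fit was tested on simulated data with 200 genes changed among 22180. For 10-day culture against quiescent it recovered 85% of changes of 1 log2 unit and 100% of changes of 2, and called 15 unchanged genes. For 4-week against 2-week CCl4 the shares were 79% and 100%, with 9 unchanged genes called. The simulated noise was drawn independently for each gene and array at the fitted spread, so these shares need not hold for the measured arrays. Between the CCl4 times, several measured differences of more than 1 log2 unit were not called. Alternatives were quantile normalization, median centring, leaving out the dimmest genes (a fraction of 0.25), the mean of a gene's probe sets, all probe sets, an intensity trend, robust variances, array weights, only the groups compared, the replicate number as a block, each array left out in turn, a 2-fold threshold, an adjusted p under 0.01, and camera with an estimated correlation or on ranks. The shift of the median gene under either normalization was at most 0.07 log2 units in size. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. When 1 array was left out, its group kept 1 array, assumed to vary like the other groups. Values without either or any array of a group are from fits that left out 1 array at a time. Counts of 5 or fewer list members often moved by more than 1.5 times then, so left-out arrays are named beside larger counts and where the call of a reported list ended or began. Labels gave no batch or date, so batches were not tested.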

Results

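Hepatic stellate cells are the vitamin A storing pericytes of the liver, which become matrix-producing myofibroblasts when the liver is injured or when they are kept on plastic. Transcript levels were measured in quiescent stellate cells of healthy BALB/c mice, an inbred strain, in cells cultured for 10 days, and in cells isolated after 2 or 4 weeks of CCl4, a hepatotoxin that produces fibrosis. There were 2 arrays per group, 8 in all. The study concerns YAP, the transcriptional coactivator restrained by the Hippo pathway, in this activation. Levels are log2 RMA values, given as mean ± SD (n = 2), and changes are log2 fold changes ± SE from limma with Benjamini-Hochberg adjusted p. List tests are limma's camera.

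Cultured, quiescent and CCl4 arrays lay apart, but the arrays of 2 and 4 weeks of CCl4 lay about as near to each other as replicates did. Over 22180 genes, the first principal component held 60.5% of the variance and set both cultured arrays (-75.2 and -80.3) apart from the 6 arrays of unseeded cells (11.3 to 51.6). The next component, with 20.1%, set the quiescent arrays (44.2 and 29.5) apart from the 4 CCl4 arrays (-32.2 to -14.5). Pearson correlations across probe sets within groups, which are not independent replicates, were 0.973 for quiescent, 0.980 for culture, 0.977 for 2-week and 0.982 for 4-week cells. Between groups they reached 0.976 to 0.978 for 2-week with 4-week arrays and 0.972 for quiescent replicate 2 with 2-week replicate 2. The quiescent pair differed most, with 565 genes more than 2-fold apart, against 158, 117 and 56 in the other groups.

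Markers of other liver cells differed between the arrays. The median hepatocyte marker stood at 10.01 and 8.60 log2 units in quiescent replicates 1 and 2, at 7.06 and 7.85 at 2 weeks of CCl4, at 6.50 and 5.98 at 4 weeks, and at 4.57 and 4.50 in culture. The median sinusoidal endothelial marker ran from 9.57 and 8.69 in quiescent cells to 7.42 and 7.79, then 6.43 and 7.07, and 5.51 and 5.22 in culture. Macrophage markers stood at 7.64 and 8.16 in quiescent cells and at 7.65 and 7.87 at 2 weeks, but at 6.42 and 6.52 at 4 weeks and 6.28 and 6.33 in culture.

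**Figure D1:**
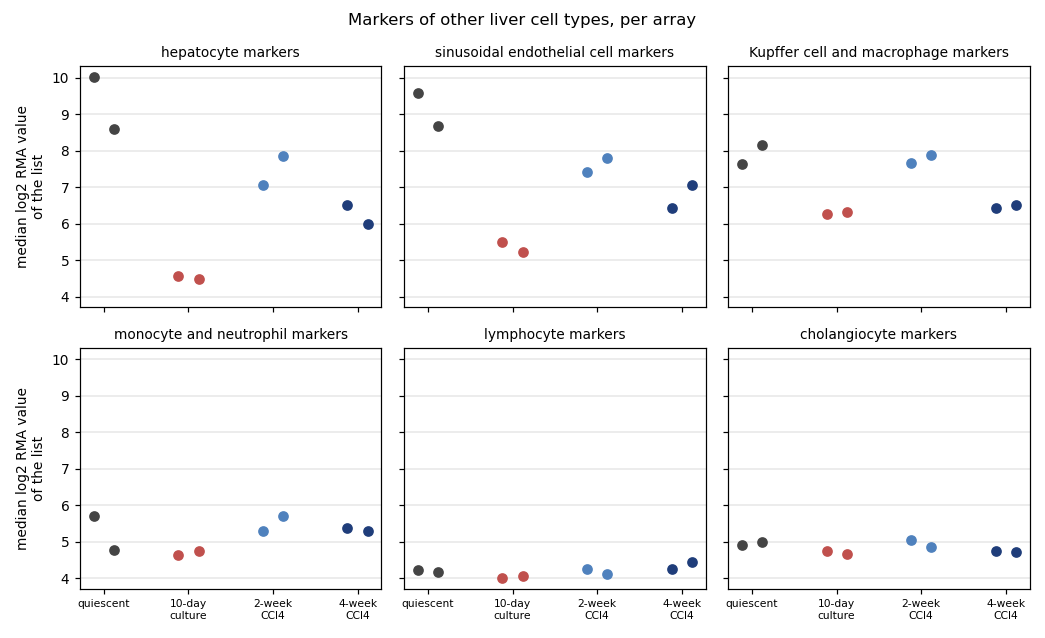
Median log2 RMA value of the markers of 6 other liver cell types (vertical axis) on each of the 8 arrays, grouped by condition (horizontal axis), each point being 1 array. Hepatocyte medians lie at 10.01 and 8.60 in quiescent cells and at 4.57 and 4.50 in culture, and macrophage medians at 7.65 and 7.87 at 2 weeks of CCl4 and at 6.42 and 6.52 at 4 weeks.

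The question of the study begins with the Hippo pathway. Yap1 (probe set 17523883) stood at 8.08 ± 0.16 in quiescent cells, 7.92 ± 0.15 in culture, 8.06 ± 0.10 at 2 weeks and 8.05 ± 0.25 at 4 weeks of CCl4, and passed the threshold in none of the 5 comparisons (adjusted p 0.59, 0.975, 0.954, 0.995 and 0.606). Wwtr1, which encodes the paralogue TAZ, did not pass against quiescent cells in culture (0.53 ± 0.18, adjusted p = 0.0589) or at either CCl4 time. It was higher in culture than after CCl4 (0.68 ± 0.15, adjusted p = 0.0123). Tead1, the DNA-binding partner of both, rose in culture (1.01 ± 0.21, adjusted p = 0.00788) and at 4 weeks (0.82 ± 0.21, adjusted p = 0.0453), with 0.51 ± 0.21 at 2 weeks (adjusted p = 0.261). The 4-week call of Tead1 was kept without quiescent replicate 2 and lost in the other 7 fits that left out 1 array (adjusted p 0.0693 to 0.269). Vgll3, another cofactor of the TEAD proteins, rose by 4.18 ± 0.25, 1.79 ± 0.25 and 2.50 ± 0.25 in culture and at 2 and 4 weeks. Ankrd1 (probe set 17364176), a widely used YAP target, rose 33.1-fold in culture and 8-fold at 4 weeks, with 1.22 ± 0.53 at 2 weeks (adjusted p = 0.287). The targets Ccn2 and Ccn1 stood at 10.62 ± 0.20 and 11.12 ± 0.54 in quiescent cells. At 2 weeks, Vgll3 (without 2-week replicate 1, adjusted p = 0.0699) lost its call with 1 array left out. At 4 weeks, Ankrd1 (without 4-week replicate 2, adjusted p = 0.0628) lost its call with 1 array left out. In culture against CCl4, Wwtr1 (without culture replicate 2, adjusted p = 0.136) lost its call with 1 array left out.

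**Figure D2:**
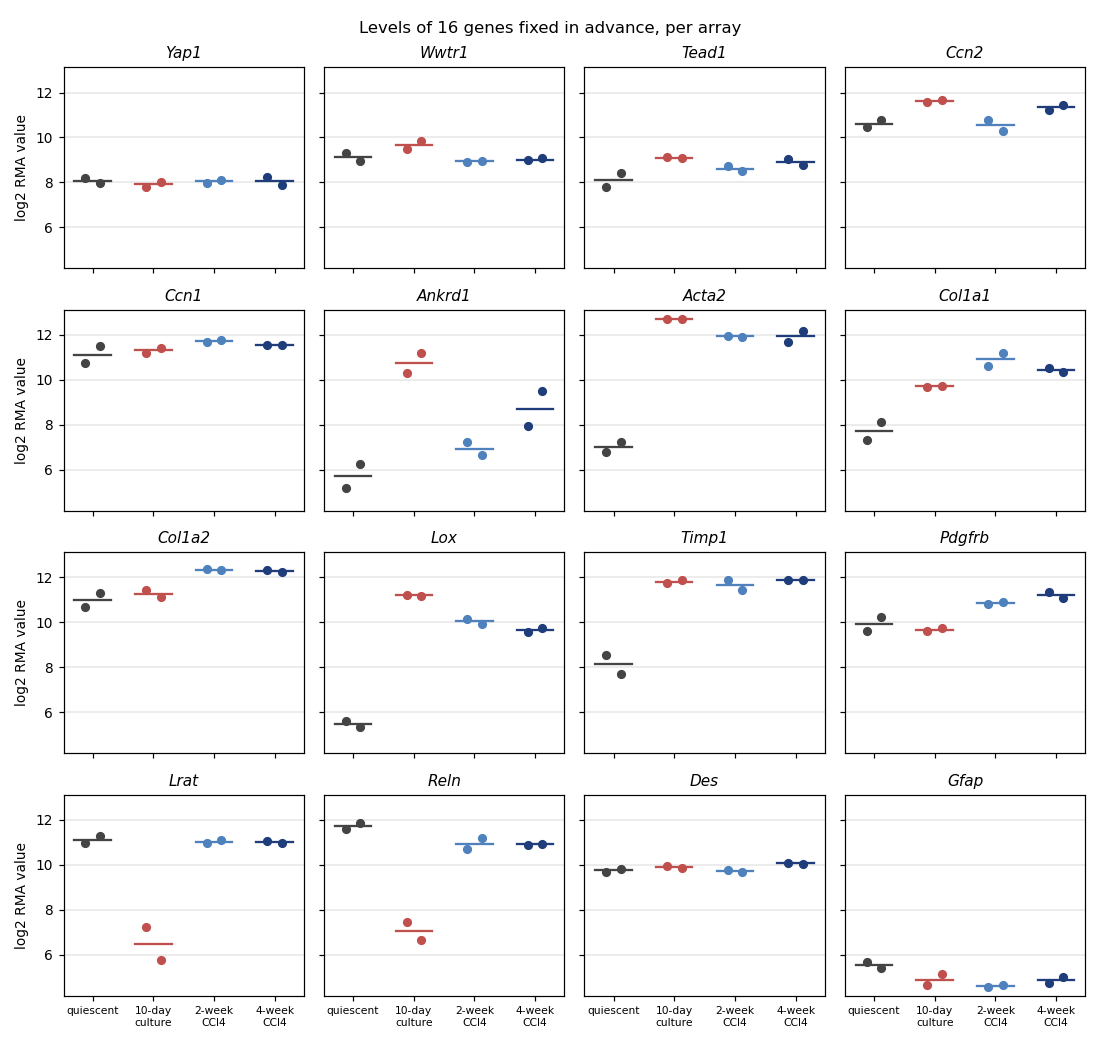
Log2 RMA values (vertical axis) of 16 genes chosen in advance in the 4 groups (horizontal axis), each point being 1 array and each bar the mean of 2. Yap1 lies at 8.08 in quiescent and 7.92 in cultured cells, while Acta2 goes from 7.01 to 12.70 and Lrat from 11.12 to 6.48.

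Genes of contraction, collagen processing and cell division were higher after 10 days of culture, and the markers of the quiescent cell were lower. With an estimated correlation, these 4 list tests gave adjusted p = 0.281, 0.299, 0.209 and 0.106. Cultured cells also differed in the markers of other liver cells and perhaps in valproic acid, which cannot be told apart from culture here. Acta2, the smooth muscle actin of myofibroblasts, rose 51.5-fold from 7.01 ± 0.33 to 12.70 ± 0.02. Lox, which crosslinks collagen, rose 53.6-fold, and the protease inhibitor Timp1 12.7-fold. Lrat, which makes the retinyl esters of vitamin A stores, fell by 4.64 ± 0.38 on the log2 scale, and the glycoprotein gene Reln by 4.67 ± 0.26. The largest rises were Sprr1a (8.01 ± 0.41), Cnn1 (7.56 ± 0.21), Tnfsf18 (6.68 ± 0.16), Cpe (6.03 ± 0.14), Tnc (5.94 ± 0.25), Mmp10 (5.82 ± 0.31), Lox (5.75 ± 0.16), Actg2 (5.74 ± 0.35), Acta2 (5.69 ± 0.20) and Ptgs2 (5.37 ± 0.34). Most of the largest falls were transcripts known from hepatocytes or endothelial cells, Saa2 (-8.76 ± 0.87), Alb (-7.47 ± 0.20), Clec4g (-7.40 ± 0.30), Steap4 (-7.37 ± 0.14), Hp (-7.31 ± 0.48), Fabp1 (-7.20 ± 0.28), Fgg (-7.10 ± 0.48), Tgfbi (-7.07 ± 0.19), Mup3 (-7.03 ± 0.36) and Hamp (-6.94 ± 0.87). In all, 2869 genes were higher and 2276 lower, 23.2% of those tested.

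YAP/TAZ target genes rose on balance in culture. Of 21 measured members, 13 rose and 4 fell (14 up, 4 down adjusted over the list alone, adjusted p = 0.000181, adjusted p = 0.264 with an estimated correlation). Besides Ankrd1, F3 (4.91 ± 0.29), Tgfb2 (4.07 ± 0.26), Dock5 (3.04 ± 0.18) and Ccn2 (1.0 ± 0.19) rose. A dimmer Ccn2 probe set (mean 5.44 against 11.03 log2 units) stood at 0.04 ± 0.24 in culture, and the mean of both gave 0.52, not past the threshold (adjusted p = 0.0659). The members that fell were Nt5e (-3.38 ± 0.20), Rbms3 (-1.19 ± 0.15), Igfbp3 (-1.15 ± 0.33) and Arhgef17 (-0.43 ± 0.14). The 4 falls became 2 without quiescent replicate 1, without culture replicate 2, and without any single CCl4 array. Ccn1 stood at 0.20 ± 0.23 (adjusted p = 0.63). Among Hippo pathway components, 8 of 25 rose and 2 fell (10 up, 3 down adjusted over the list alone, adjusted p = 0.0352, adjusted p = 0.209 with an estimated correlation). Vgll3, Amot (1.31 ± 0.20) and Stk4 (1.24 ± 0.19) were among the rises, while the protocadherin gene Dchs1 (-1.16 ± 0.20) and Vgll4 (-0.67 ± 0.18) fell. That list call was lost without quiescent replicate 2 (adjusted p = 0.0546) or culture replicate 2 (adjusted p = 0.0931). Arhgef17 (in 8 of the 8 fits, adjusted p 0.0537 to 0.195), Igfbp3 (in 6 of the 8 fits, adjusted p 0.0502 to 0.24) and Vgll4 (in 3 of the 8 fits, adjusted p 0.0556 to 0.159) lost their calls with 1 array left out.

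Contractile genes rose as a group in culture. Of 26 genes of the actin cytoskeleton, 21 rose and 0 fell (23 up, 0 down adjusted over the list alone, adjusted p = 8.36e-13, adjusted p = 0.281 with an estimated correlation), with the calponin gene Cnn1 (7.56 ± 0.21), Lmod1 (3.84 ± 0.21) and Tpm1 (3.34 ± 0.18) beside Acta2. Without quiescent replicate 1, 1 member fell. Vascular smooth muscle markers, which overlap with it, gave 8 rises and 3 falls of 17 (8 up, 3 down adjusted over the list alone, adjusted p = 0.0083, adjusted p = 0.398 with an estimated correlation). The falls were Rgs4 (-3.89 ± 0.25), Itga8 (-2.94 ± 0.30) and Pln (-0.51 ± 0.16). Of 23 activated stellate cell markers, 14 rose and 1 fell (14 up, 2 down adjusted over the list alone, adjusted p = 7.81e-07, adjusted p = 0.209 with an estimated correlation), among them Tnc (5.94 ± 0.25) and Ltbp2 (3.86 ± 0.17). Mgp, a matrix Gla protein gene, was the member that fell (-2.07 ± 0.44). The falls numbered 3 without quiescent replicate 1 and 0 without culture replicate 2. Pln (in 7 of the 8 fits, adjusted p 0.0619 to 0.264) and Mgp (without culture replicate 2, adjusted p = 0.0518) lost their calls with 1 array left out.

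Collagen genes went both ways in culture. Of 23 collagens, 8 rose and 4 fell (8 up, 6 down adjusted over the list alone, adjusted p = 0.617), with a mean of 0.29 and a median of -0.03. Col1a1 rose 3.92-fold with Col12a1 (4.66 ± 0.24) and Col4a5 (3.12 ± 0.21), whereas Col14a1 (-4.70 ± 0.32), Col6a3 (-3.35 ± 0.31), Col6a1 (-2.45 ± 0.17) and Col6a2 (-1.90 ± 0.25) fell. Col1a2 stood at 0.28 ± 0.21 (adjusted p = 0.433), and a dimmer Col1a2 probe set (mean 9.39 against 11.73 log2 units) at -0.34 ± 0.26. Genes of collagen processing gave 10 rises and 2 falls of 17 (11 up, 3 down adjusted over the list alone, adjusted p = 0.00261, adjusted p = 0.299 with an estimated correlation), with Plod2 (1.56 ± 0.14), P4ha2 (1.32 ± 0.16) and P3h1 (1.21 ± 0.14) against Plod1 (-0.95 ± 0.16) and Pcolce (-0.94 ± 0.23). Matrix metalloproteinases and their inhibitors split into 8 rises and 5 falls of 19 (9 up, 5 down adjusted over the list alone, adjusted p = 0.298), with Mmp10 (5.82 ± 0.31), Mmp13 (3.01 ± 0.21) and Mmp12 (2.54 ± 0.13) against Adamts1 (-2.70 ± 0.19), Mmp2 (-2.46 ± 0.24) and Reck (-2.22 ± 0.24). Integrin and focal adhesion genes gave 9 rises and 5 falls of 21 (11 up, 5 down adjusted over the list alone, adjusted p = 0.0978), with Itga5 (3.14 ± 0.25), Itga4 (2.90 ± 0.17) and Itga2 (2.36 ± 0.15) against Itgb8 (-3.08 ± 0.26), Itga8 (-2.94 ± 0.30) and Itgb3 (-2.01 ± 0.40). TGF-beta genes gave 4 rises and 7 falls of 23 (4 up, 9 down adjusted over the list alone, adjusted p = 0.141), with the ligands Tgfb3 (4.47 ± 0.26) and Tgfb2 (4.07 ± 0.26) against Tgfbi (-7.07 ± 0.19) and Tgfbr3 (-3.99 ± 0.15). Integrin rises numbered 5 without quiescent replicate 1 or culture replicate 2, and that list passed without quiescent replicate 2 (adjusted p = 0.0326). Pcolce (without quiescent replicate 2, adjusted p = 0.078 and without culture replicate 2, adjusted p = 0.121) lost its call with 1 array left out.

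Quiescent stellate cell markers fell together in culture. Of 24 measured, 21 fell and 1 rose (1 up, 21 down adjusted over the list alone, adjusted p = 5.04e-21, adjusted p = 0.106 with an estimated correlation), led by Colec10 (-6.08 ± 0.15), Rgs5 (-5.70 ± 0.14), Vipr1 (-5.36 ± 0.19) and Hgf (-5.18 ± 0.13). Nes, the intermediate filament gene nestin, was the member that rose (3.44 ± 0.54). Des, which encodes desmin, stood at 0.17 ± 0.13 and Pdgfrb at -0.25 ± 0.20, neither past the threshold. Retinoid genes gave 5 rises and 8 falls of 23 (6 up, 8 down adjusted over the list alone, adjusted p = 0.275), with Rbp4 (-2.40 ± 0.21) and Rxra (-1.45 ± 0.16) against Rarb (1.67 ± 0.15) and Cyp26b1 (1.37 ± 0.36). Lipid droplet and lipid metabolism genes gave 8 falls and 2 rises of 23 (3 up, 9 down adjusted over the list alone, adjusted p = 0.00768, adjusted p = 0.236 with an estimated correlation). Fabp4 (-4.31 ± 0.51), G0s2 (-4.18 ± 0.25), Lpl (-2.75 ± 0.25) and Cd36 (-2.61 ± 0.31) fell, and Fabp5 (1.81 ± 0.28) and Abhd5 (0.85 ± 0.17) rose. Hedgehog genes gave 5 falls and 1 rise of 13 (1 up, 5 down adjusted over the list alone, adjusted p = 0.0457, adjusted p = 0.391 with an estimated correlation), with Hhip (-3.95 ± 0.20) and Ptch1 (-1.78 ± 0.25) against Boc (0.99 ± 0.14). That call was lost without quiescent replicate 2 (adjusted p = 0.114), culture replicate 2 (0.0648) or 4-week replicate 1 (0.051) or 2 (0.0521). Retinoid falls numbered 5 without any 1 array other than quiescent replicate 1, and lipid falls 5 or 4 without culture replicate 1 or 2. Cyp26b1 (in 3 of the 8 fits, adjusted p 0.062 to 0.151) and Abhd5 (without culture replicate 1, adjusted p = 0.051) lost their calls with 1 array left out.

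Proliferation genes rose in culture, 21 of 24 with 0 falls (21 up, 0 down adjusted over the list alone, adjusted p = 1.41e-12, adjusted p = 0.209 with an estimated correlation), including Rrm2 (4.12 ± 0.14), Birc5 (3.27 ± 0.18), Tpx2 (2.43 ± 0.14) and Mcm6 (1.91 ± 0.14). Cholesterol biosynthesis gave 8 rises of 16 (8 up, 0 down adjusted over the list alone, adjusted p = 0.000687, adjusted p = 0.414 with an estimated correlation), among them Cyp51 (1.86 ± 0.41), Msmo1 (1.65 ± 0.39), Fdps (1.45 ± 0.31) and Sc5d (1.36 ± 0.19). Oxidative phosphorylation gave 13 rises of 22 (17 up, 0 down adjusted over the list alone, adjusted p = 3.98e-05, adjusted p = 0.236 with an estimated correlation), each small, such as Cox5a (0.93 ± 0.14) and Uqcrc1 (0.65 ± 0.13). These last counts leaned on single arrays, with 4 and 2 cholesterol genes without culture replicate 1 or 2 and 3 without quiescent replicate 2. The oxidative phosphorylation rises numbered 4 and 1 without culture replicate 1 or 2, 5 without quiescent replicate 1 and 7 without either 4-week array. Glycolysis and hypoxia genes gave 10 rises and 1 fall of 20 (12 up, 1 down adjusted over the list alone, adjusted p = 5.34e-06, adjusted p = 0.106 with an estimated correlation), with Vegfa (2.65 ± 0.19), Pgk1 (1.99 ± 0.13) and Hk2 (1.74 ± 0.17) against Ndrg1 (-2.56 ± 0.39). Msmo1 (without quiescent replicate 2, adjusted p = 0.0666 and without culture replicate 2, adjusted p = 0.0888), Cyp51 (without culture replicate 2, adjusted p = 0.0659), Fdps (without culture replicate 2, adjusted p = 0.0671) and Uqcrc1 (without culture replicate 2, adjusted p = 0.0531) lost their calls with 1 array left out. Unfolded protein response genes gave 1 rise and 3 falls of 21 (0 up, 3 down adjusted over the list alone, adjusted p = 0.486).

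Immediate early genes, which cells induce within minutes of stress, fell in culture. Of 24, 21 fell and 0 rose (0 up, 22 down adjusted over the list alone, adjusted p = 9.86e-22, adjusted p = 0.115 with an estimated correlation), with Fosb (-5.87 ± 0.16), Socs3 (-5.05 ± 0.17), Nr4a1 (-4.92 ± 0.19) and Fos (-4.74 ± 0.14). Fos stood at 10.58 ± 0.13 in quiescent cells, 10.43 ± 0.08 and 10.52 ± 0.02 at 2 and 4 weeks of CCl4 and 5.84 ± 0.10 in culture. Interferon response genes gave 14 falls and 0 rises of 21 (0 up, 18 down adjusted over the list alone, adjusted p = 6.79e-11, adjusted p = 0.145 with an estimated correlation). The falls included Irf1 (-3.18 ± 0.21), Oas2 (-2.80 ± 0.24) and Psmb9 (-2.19 ± 0.15). Cytokine and chemokine genes gave 15 falls and 4 rises of 25 (4 up, 17 down adjusted over the list alone, adjusted p = 2.32e-06, adjusted p = 0.209 with an estimated correlation). Cxcl1 (-5.12 ± 0.23) and Il34 (-3.37 ± 0.17) fell, while Ptgs2 (5.37 ± 0.34), Cxcl14 (3.52 ± 0.44), Il6 (3.46 ± 0.33) and Csf1 (2.23 ± 0.15) rose.

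Markers of other cells were measured beside these groups. Of 24 hepatocyte markers 21 fell (0 up, 21 down adjusted over the list alone, adjusted p = 2.04e-19, adjusted p = 0.208 with an estimated correlation). Of 24 sinusoidal endothelial markers, 23 fell (0 up, 24 down adjusted over the list alone, adjusted p = 5.78e-22, adjusted p = 0.203 with an estimated correlation). Macrophage markers gave 18 falls and 1 rise of 22 (2 up, 18 down adjusted over the list alone, adjusted p = 2.24e-09, adjusted p = 0.208 with an estimated correlation). The rise was that of the lysozyme gene Lyz2 (0.93 ± 0.19). Monocyte and neutrophil markers gave 5 falls and 1 rise of 17 (1 up, 5 down adjusted over the list alone, adjusted p = 0.00719, adjusted p = 0.541 with an estimated correlation). That call was lost without quiescent replicate 1 (adjusted p = 0.204). Cholangiocyte markers gave 6 falls and 1 rise of 13 (1 up, 6 down adjusted over the list alone, adjusted p = 0.0143, adjusted p = 0.231 with an estimated correlation). Portal fibroblast and mesothelial markers gave 9 falls and 3 rises of 21 (4 up, 10 down adjusted over the list alone, adjusted p = 0.0239, adjusted p = 0.287 with an estimated correlation), with Dpt (-6.68 ± 0.18) and Cd34 (-2.20 ± 0.21) against Fbln2 (4.45 ± 0.27) and Mfap5 (3.72 ± 0.33). Of 20 lymphocyte markers, none passed by itself (0 up, 0 down adjusted over the list alone, adjusted p = 0.0352, adjusted p = 0.209 with an estimated correlation), and the limma count at an unadjusted p under 0.05 over all genes was 7323. List calls were lost without quiescent replicate 2 (adjusted p = 0.0894) or culture replicate 1 (0.0724) for lymphocytes, and without culture replicate 2 (0.119) for portal fibroblasts. Cholangiocyte falls numbered 2 without culture replicate 1. The 4 sex-linked genes measured did not pass, with Xist (-0.26 ± 0.17) and Eif2s3y (0.46 ± 0.16).

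After 2 weeks of CCl4, fewer genes had changed from the quiescent level than in culture. Tnc, a matrix glycoprotein of wounds, rose 38.8-fold, Acta2 30.4-fold, Lox 24-fold and Timp1 11.5-fold. Both type I collagen genes rose, Col1a1 9.04-fold and Col1a2 2.56-fold, as did Pdgfrb, the receptor for platelet-derived growth factor (0.91 ± 0.20). The dimmer Col1a2 probe set rose by 2.55 ± 0.26 on the log2 scale, against 1.35 for the one used. Lrat stood at -0.09 ± 0.38 and Reln at -0.77 ± 0.26, not past the threshold. Other large rises were Rgs16 (4.78 ± 0.33), Col12a1 (4.26 ± 0.24), Ch25h (4.15 ± 0.22), Gpnmb (4.04 ± 0.24), Ltbp2 (4.03 ± 0.17), Ptgs2 (4.0 ± 0.34) and Ncam1 (3.63 ± 0.35). The largest falls were mostly secreted proteins known from liver, Saa2 (-4.80 ± 0.87), Obp2a (-4.78 ± 0.46), Orm2 (-4.24 ± 0.84), Mup20 (-4.23 ± 0.51), Saa4 (-3.77 ± 0.76), Tmem108 (-3.70 ± 0.49), Apcs (-3.33 ± 0.59), Orm1 (-3.31 ± 0.45), Serpina10 (-3.31 ± 0.58) and Itih4 (-3.29 ± 0.56). There were 520 genes higher and 538 lower. Without 2-week replicate 1 these counts were 190 and 70, without 2-week replicate 2 they were 274 and 249, and without either 4-week array the lower count was 315. A fit of the compared groups alone gave 227 and 145. Pdgfrb (in 7 of the 8 fits, adjusted p 0.0706 to 0.182), Saa4 (in 6 of the 8 fits, adjusted p 0.0525 to 0.195), Orm2 (in 4 of the 8 fits, adjusted p 0.0566 to 0.206), Col1a2 (without 2-week replicate 1, adjusted p = 0.0787 and without 2-week replicate 2, adjusted p = 0.0517), Apcs (without 2-week replicate 1, adjusted p = 0.122 and without 2-week replicate 2, adjusted p = 0.0882), Itih4 (without 2-week replicate 1, adjusted p = 0.122 and without 2-week replicate 2, adjusted p = 0.0668), Serpina10 (without 2-week replicate 1, adjusted p = 0.139 and without 2-week replicate 2, adjusted p = 0.0613), Orm1 (without 2-week replicate 1, adjusted p = 0.0563) and Saa2 (without quiescent replicate 1, adjusted p = 0.069) lost their calls with 1 array left out.

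YAP/TAZ target genes did not pass as a list at 2 weeks. Of 21, 4 rose and 1 fell (6 up, 3 down adjusted over the list alone, adjusted p = 0.155). The rises included Tgfb2 (1.95 ± 0.26), Ccdc80 (1.72 ± 0.15) and Axl (0.83 ± 0.14), and Nt5e fell (-2.20 ± 0.20). The list test passed without quiescent replicate 2 (adjusted p = 0.0161), and 2 members rose without either 2-week array. Among Hippo components Vgll3 alone passed of 25 (2 up, 0 down adjusted over the list alone, adjusted p = 0.928), with a mean of 0.03, a median of -0.12 and a downward test. Axl (in 3 of the 8 fits, adjusted p 0.0516 to 0.0755) lost its call with 1 array left out.

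At 2 weeks, activated markers gave 16 rises and 0 falls of 23 (19 up, 1 down adjusted over the list alone, adjusted p = 4.8e-25, adjusted p = 0.106 with an estimated correlation). Collagens gave 13 rises and 0 falls of 23 (16 up, 0 down adjusted over the list alone, adjusted p = 1.45e-17, adjusted p = 0.194 with an estimated correlation), including Col1a1 (3.18 ± 0.27), Col15a1 (2.88 ± 0.19) and Col4a2 (1.62 ± 0.15). Collagen processing gave 6 rises of 17 (8 up, 0 down adjusted over the list alone, adjusted p = 1.92e-07, adjusted p = 0.208 with an estimated correlation), with Loxl1 (1.63 ± 0.24), Plod2 (1.32 ± 0.14) and P3h1 (1.26 ± 0.14). Metalloproteinases and inhibitors gave 7 rises of 19 (12 up, 1 down adjusted over the list alone, adjusted p = 4.37e-09, adjusted p = 0.106 with an estimated correlation), with Mmp12 (3.34 ± 0.13), Mmp19 (2.75 ± 0.17) and Mmp14 (1.16 ± 0.14). Actin genes gave 12 rises of 26 (20 up, 0 down adjusted over the list alone, adjusted p = 3.37e-16, adjusted p = 0.233 with an estimated correlation), with Tpm1 (2.29 ± 0.18), Cnn1 (1.98 ± 0.21) and Myh10 (1.55 ± 0.21). Smooth muscle markers gave 7 rises and 2 falls of 17 (11 up, 2 down adjusted over the list alone, adjusted p = 3.55e-06, adjusted p = 0.209 with an estimated correlation), Rgs4 (-2.16 ± 0.25) and Pln (-0.66 ± 0.16) being the falls. These counts fell without 2-week replicates 1 and 2 in turn, to 7 and 7 for collagens and 3 and 6 for actin genes. Activated markers fell to 10 without 2-week replicate 2, and actin genes rose to 20 without quiescent replicate 2. Collagen processing and smooth muscle rises both numbered 3 without either 2-week array. Portal fibroblast and mesothelial markers also rose, 7 of 21 (8 up, 1 down adjusted over the list alone, adjusted p = 2.85e-05, adjusted p = 0.179 with an estimated correlation), with Mfap4 (2.24 ± 0.19), Wt1 (1.78 ± 0.24) and Dpt (1.28 ± 0.18), and 4 without 2-week replicate 1. Pln (in 8 of the 8 fits, adjusted p 0.0504 to 0.242), Loxl1 (without 2-week replicate 1, adjusted p = 0.0611 and without 2-week replicate 2, adjusted p = 0.0578) and Myh10 (without 2-week replicate 1, adjusted p = 0.0547) lost their calls with 1 array left out.

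Quiescent markers fell at 2 weeks, 13 of 24 with 0 rises (1 up, 17 down adjusted over the list alone, adjusted p = 3.28e-12, adjusted p = 0.115 with an estimated correlation), led by Hhip (-3.20 ± 0.20), Vipr1 (-2.13 ± 0.19) and Colec10 (-1.30 ± 0.15). The count was 4 or 6 without 2-week replicate 1 or 2, and 8 without either 4-week array. Inflammatory genes gave 6 rises and 1 fall of 25 (7 up, 1 down adjusted over the list alone, adjusted p = 0.0019, adjusted p = 0.299 with an estimated correlation), with Il6 (3.61 ± 0.33) and Ccl7 (2.03 ± 0.22) against Il34 (-1.68 ± 0.17). Glycolysis and hypoxia genes gave 7 rises of 20 (11 up, 1 down adjusted over the list alone, adjusted p = 4.47e-06, adjusted p = 0.106 with an estimated correlation), with Hk2 (2.57 ± 0.17) and Vegfa (1.26 ± 0.19). These rises numbered 1 and 2 without 2-week replicate 1 or 2, and 4 without quiescent replicate 1 or either 4-week array, and the inflammatory rises 3 without 2-week replicate 1. Integrins gave 3 rises and 1 fall of 21 (4 up, 1 down adjusted over the list alone, adjusted p = 0.0399, adjusted p = 0.411 with an estimated correlation). This call was lost when any 1 array other than quiescent replicate 2 or a 4-week array was left out (adjusted p 0.0591 to 0.431). Immediate early genes gave 0 rises and 0 falls of 24 (1 up, 2 down adjusted over the list alone, adjusted p = 0.29). Proliferation genes gave 1 rise, Mcm6 (1.28 ± 0.14), of 24 (1 up, 0 down adjusted over the list alone, adjusted p = 0.302), a list that passed without quiescent replicate 2 (adjusted p = 0.0349). Among marker lists of other cells, 13 of 24 hepatocyte markers fell (0 up, 17 down adjusted over the list alone, adjusted p = 3.18e-15, adjusted p = 0.209 with an estimated correlation). Of 24 endothelial markers, 16 fell (0 up, 21 down adjusted over the list alone, adjusted p = 2.04e-19, adjusted p = 0.208 with an estimated correlation). Without 2-week replicate 1 these falls numbered 0 and 1, without 2-week replicate 2 7 and 4, and without quiescent replicate 1 the endothelial falls numbered 9. Macrophage markers gave 3 rises and 2 falls of 22 (6 up, 2 down adjusted over the list alone, adjusted p = 0.703), with Cd68 (1.02 ± 0.16) and Ctss (0.81 ± 0.14) against Timd4 (-1.32 ± 0.20) and Cd163 (-1.15 ± 0.17), a mean of -0.02, a median of -0.09 and an upward test. Ctss (in 3 of the 8 fits, adjusted p 0.0607 to 0.077), Vegfa (without 2-week replicate 1, adjusted p = 0.0631 and without 2-week replicate 2, adjusted p = 0.0517), Cd68 (without 2-week replicate 2, adjusted p = 0.0648), Cd163 (without 2-week replicate 1, adjusted p = 0.0566) and Timd4 (without 2-week replicate 1, adjusted p = 0.0734) lost their calls with 1 array left out.

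After 4 weeks of CCl4, Tnc rose 49.1-fold, Acta2 30.5-fold, Lox 18.3-fold, Timp1 13.5-fold, Col1a1 6.51-fold and Col1a2 2.43-fold. The dimmer Col1a2 probe set rose by 2.05 ± 0.26 on the log2 scale, against 1.28 for the one used. Pdgfrb rose 2.42-fold, and Lrat stood at -0.11 ± 0.38 (adjusted p = 0.926). Further large rises were Ch25h (4.83 ± 0.22), Rgs16 (4.37 ± 0.33), Col12a1 (4.21 ± 0.24), Cxcl14 (4.10 ± 0.44), Sytl2 (4.09 ± 0.23), Fhl2 (4.0 ± 0.14) and Chst11 (3.92 ± 0.18). The largest falls were again liver secretory transcripts, Saa2 (-7.59 ± 0.87), Fgg (-5.10 ± 0.48), Mup20 (-5.08 ± 0.51), Obp2a (-4.95 ± 0.46), Orm2 (-4.64 ± 0.84), Mup3 (-4.59 ± 0.36), Pzp (-4.50 ± 0.45), Saa4 (-4.48 ± 0.76), Apcs (-4.35 ± 0.59) and Fga (-4.28 ± 0.52). There were 896 genes higher and 1036 lower. The counts were 317 and 335 without 4-week replicate 1, 350 and 377 without 4-week replicate 2, and 552 and 653 in a fit of the compared groups alone. A dimmer Ch25h probe set (mean 4.79 against 8.89) did not pass at 2 weeks (0.39 ± 0.22) or 4 weeks (0.47 ± 0.22). Orm2 (without 4-week replicate 1, adjusted p = 0.0701 and without 4-week replicate 2, adjusted p = 0.0917), Saa4 (without 4-week replicate 1, adjusted p = 0.0712 and without 4-week replicate 2, adjusted p = 0.0648), Col1a2 (without 4-week replicate 1, adjusted p = 0.0669) and Pdgfrb (without 4-week replicate 1, adjusted p = 0.0692) lost their calls with 1 array left out.

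YAP/TAZ target genes rose on balance at 4 weeks. Of 21, 7 rose and 1 fell (9 up, 2 down adjusted over the list alone, adjusted p = 0.00164, adjusted p = 0.299 with an estimated correlation). Ankrd1 (3.0 ± 0.53), Ccn2 (0.73 ± 0.19), Tgfb2 (1.89 ± 0.26), Ccdc80 (1.59 ± 0.15) and Axl (1.39 ± 0.14) rose and Nt5e fell (-2.03 ± 0.20). There were 4 rises without 4-week replicate 2, and 2 falls without quiescent replicate 2. The dimmer Ccn2 probe set stood at 0.16 ± 0.24. Hippo components gave 5 rises of 25 (6 up, 0 down adjusted over the list alone, adjusted p = 0.144), with Vgll3, Map4k4 (1.08 ± 0.13), Tead3 (0.87 ± 0.15) and Frmd6 (0.69 ± 0.16). Ccn2 (in 5 of the 8 fits, adjusted p 0.0755 to 0.252), Frmd6 (in 5 of the 8 fits, adjusted p 0.0526 to 0.215), Ankrd1 (without 4-week replicate 2, adjusted p = 0.0628) and Tead3 (without 4-week replicate 2, adjusted p = 0.0763) lost their calls with 1 array left out.

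Activated markers gave 17 rises of 23 at 4 weeks (19 up, 0 down adjusted over the list alone, adjusted p = 3.55e-22, adjusted p = 0.109 with an estimated correlation). Collagens gave 14 of 23 (14 up, 0 down adjusted over the list alone, adjusted p = 2.8e-12, adjusted p = 0.209 with an estimated correlation), with Col15a1 (3.47 ± 0.19) and Col4a2 (1.94 ± 0.15). Collagen processing gave 7 of 17 (7 up, 0 down adjusted over the list alone, adjusted p = 1.27e-05, adjusted p = 0.209 with an estimated correlation). Metalloproteinases gave 9 rises and 1 fall of 19 (10 up, 1 down adjusted over the list alone, adjusted p = 7.78e-08, adjusted p = 0.106 with an estimated correlation), with Mmp19 (3.17 ± 0.17), Mmp12 (2.08 ± 0.13) and Mmp14 (1.65 ± 0.14) against Reck (-1.02 ± 0.24). Actin genes gave 17 rises of 26 (23 up, 0 down adjusted over the list alone, adjusted p = 2.02e-21, adjusted p = 0.209 with an estimated correlation), with Tpm1 (2.28 ± 0.18), Lmod1 (1.98 ± 0.21) and Myh10 (1.79 ± 0.21). Smooth muscle markers gave 9 rises and 1 fall of 17 (10 up, 2 down adjusted over the list alone, adjusted p = 5.16e-07, adjusted p = 0.209 with an estimated correlation). Without 4-week replicate 1 there were 10 activated markers, 6 collagens and 11 actin genes higher, and without 4-week replicate 2 there were 8 collagens and 11 actin genes. Smooth muscle rises numbered 5 without either 4-week array, and collagen processing rises 3 without 4-week replicate 1. Integrins gave 5 rises and 1 fall of 21 (6 up, 1 down adjusted over the list alone, adjusted p = 0.00475, adjusted p = 0.299 with an estimated correlation), with Itga5 (2.36 ± 0.25) and Itga11 (1.16 ± 0.19) against Itgb3 (-2.16 ± 0.40). Their call was lost without quiescent replicate 1 (adjusted p = 0.0736). Genes of the unfolded protein response gave 5 rises of 21 (5 up, 0 down adjusted over the list alone, adjusted p = 0.00214, adjusted p = 0.299 with an estimated correlation), with Hyou1 (1.17 ± 0.15), Pdia6 (0.64 ± 0.13) and Hspa5 (0.61 ± 0.15), which numbered 1 without quiescent replicate 1 or either 4-week array. Portal fibroblast and mesothelial markers gave 6 rises and 1 fall of 21 (6 up, 1 down adjusted over the list alone, adjusted p = 0.00419, adjusted p = 0.209 with an estimated correlation). Hspa5 (in 6 of the 8 fits, adjusted p 0.0624 to 0.19), Reck (in 5 of the 8 fits, adjusted p 0.056 to 0.204), Pdia6 (in 3 of the 8 fits, adjusted p 0.0857 to 0.115), Itgb3 (without 4-week replicate 1, adjusted p = 0.103 and without 4-week replicate 2, adjusted p = 0.063) and Itga11 (without 4-week replicate 1, adjusted p = 0.0622) lost their calls with 1 array left out.

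Quiescent markers gave 14 falls and 1 rise of 24 at 4 weeks (2 up, 17 down adjusted over the list alone, adjusted p = 8.96e-11, adjusted p = 0.136 with an estimated correlation), with Hhip (-2.64 ± 0.20), Vipr1 (-2.41 ± 0.19), Pth1r (-1.62 ± 0.21) and Colec10 (-1.47 ± 0.15) and, against the list, Nes (2.46 ± 0.54). The falls numbered 5 without either 4-week array and 9 without quiescent replicate 1. Glycolysis and hypoxia genes gave 8 rises and 1 fall of 20 (10 up, 1 down adjusted over the list alone, adjusted p = 5.71e-06, adjusted p = 0.106 with an estimated correlation), the rises numbering 3 and 4 without 4-week replicate 1 or 2. Proliferation genes gave 0 rises and 0 falls of 24 (0 up, 0 down adjusted over the list alone, adjusted p = 0.116), and the list passed, downward, without quiescent replicate 1 (adjusted p = 0.0142). Immediate early genes gave 4 falls of 24 (1 up, 9 down adjusted over the list alone, adjusted p = 0.0168, adjusted p = 0.468 with an estimated correlation), with Socs3 (-0.99 ± 0.17), Ier2 (-0.84 ± 0.20), Atf3 (-0.78 ± 0.20) and Klf2 (-0.62 ± 0.14). This call was lost without quiescent replicate 1 (adjusted p = 0.171) or 4-week replicate 1 (adjusted p = 0.051). Interferon genes split into 2 rises, Bst2 (1.43 ± 0.19) and Irf7 (1.36 ± 0.19), and 2 falls, Irf1 (-1.49 ± 0.21) and Psmb9 (-1.01 ± 0.15), of 21 (3 up, 2 down adjusted over the list alone, adjusted p = 0.21). Hepatocyte markers gave 21 falls of 24 (0 up, 21 down adjusted over the list alone, adjusted p = 2.03e-20, adjusted p = 0.203 with an estimated correlation). Endothelial markers gave 19 of 24 (0 up, 22 down adjusted over the list alone, adjusted p = 5.78e-22, adjusted p = 0.203 with an estimated correlation). Macrophage markers gave 13 of 22 (0 up, 16 down adjusted over the list alone, adjusted p = 2.36e-15, adjusted p = 0.145 with an estimated correlation), led by Vsig4 (-4.10 ± 0.33), Timd4 (-2.52 ± 0.20) and C1qb (-1.77 ± 0.18). Endothelial falls numbered 12 without 4-week replicate 1. The monocyte and neutrophil list did not pass (2 up, 0 down adjusted over the list alone, adjusted p = 0.878), with a mean of -0.21, a median of 0.02 and an upward test. Leaving out quiescent replicate 1 or 2 gave opposite list calls, with means of 0.31 and -0.74. A dimmer Socs3 probe set stood at -0.66 ± 0.19 (adjusted p = 0.132). Atf3 (in 6 of the 8 fits, adjusted p 0.0639 to 0.281), Ier2 (in 5 of the 8 fits, adjusted p 0.0556 to 0.228), Klf2 (in 4 of the 8 fits, adjusted p 0.0563 to 0.172), Nes (in 4 of the 8 fits, adjusted p 0.0503 to 0.157) and Socs3 (without 4-week replicate 1, adjusted p = 0.0803) lost their calls with 1 array left out.

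**Figure D3:**
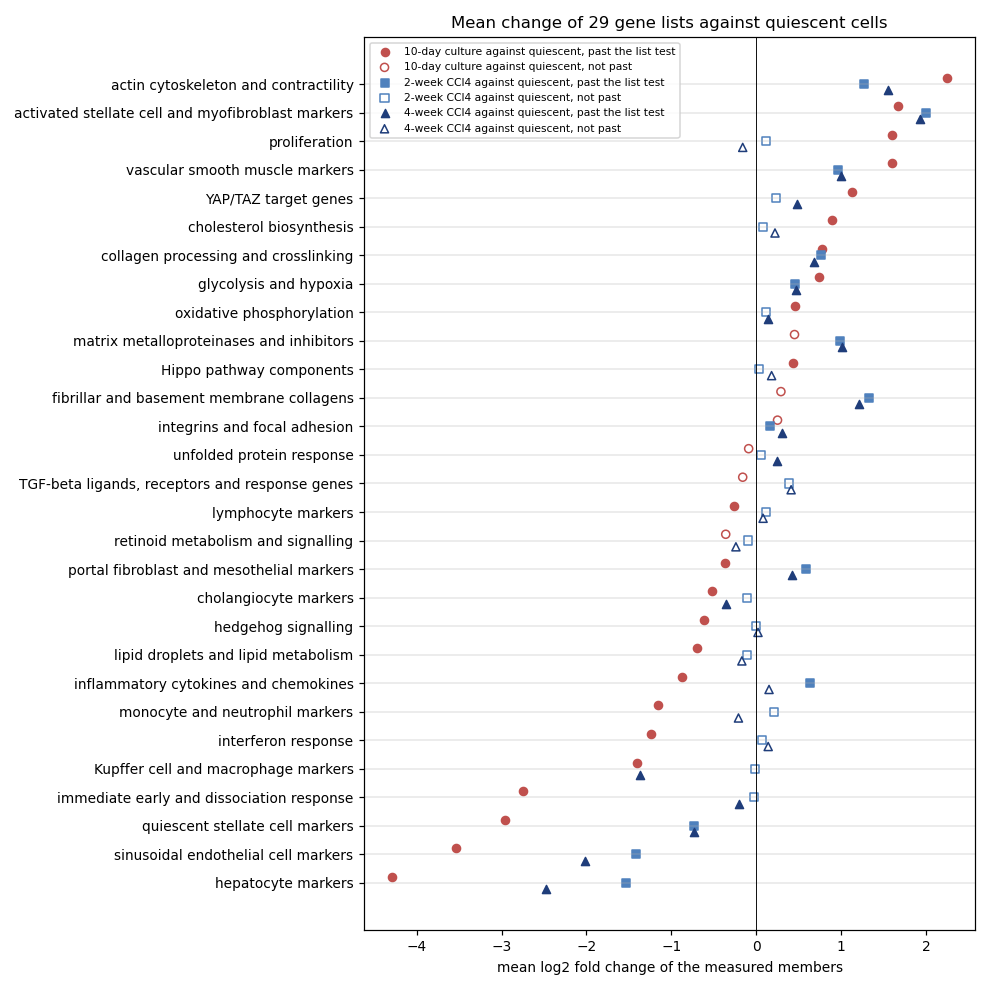
Mean log2 fold change against quiescent cells (horizontal axis) of the measured members of 29 gene lists (rows) in culture and at 2 and 4 weeks of CCl4, filled where the list test with its preset correlation passed, which no list did with an estimated correlation. Hepatocyte markers lie at -4.29, -1.54 and -2.48, actin genes at 2.25, 1.27 and 1.55, and proliferation genes at 1.60, 0.11 and -0.16.

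Between the CCl4 times, macrophage genes were lower at 4 weeks than at 2 (adjusted p = 0.106 with an estimated correlation). Vsig4, the complement receptor of Kupffer cells, fell by 3.42 ± 0.33 on the log2 scale, from 8.47 ± 0.21 to 5.05 ± 0.66. Other falls included Atp6v0d2 (-2.57 ± 0.32), Clec12a (-1.93 ± 0.21), Gpr65 (-1.71 ± 0.19), C1qb (-1.65 ± 0.18), Csf1r (-1.13 ± 0.13), Ctss (-1.22 ± 0.14) and Mmp12 (-1.26 ± 0.13), each at an adjusted p of 0.0321 or 0.0344, with the replication gene Mcm6 (-1.16 ± 0.14). Chst11, a chondroitin sulfotransferase gene, and the protease inhibitor gene Serpinb9b rose (1.35 ± 0.18 and 1.29 ± 0.16). A dimmer Serpinb9b probe set (mean 5.6 against 6.77 log2 units) stood at 0.08 ± 0.16, which is no rise. Rabggtb also rose (1.06 ± 0.14) but its 2-week level of 4.08 ± 0.16 lay below the 95th percentile of the receptor genes. In all, 6 genes were higher and 13 lower, with 1810 at an unadjusted p under 0.05. Quantile normalization gave 6 and 24. Without either quiescent array the counts were 15 and 70, without 4-week replicate 1 they were 0 and 2, and without any other CCl4 or culture array both were 0. The fit of the compared groups alone gave 14 and 68.

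Of 22 macrophage markers, 5 fell (0 up, 22 down adjusted over the list alone, adjusted p = 4.74e-36, adjusted p = 0.106 with an estimated correlation), and all 22 had both 2-week arrays above both 4-week arrays, where chance parts 2 arrays from 2, in either direction, in a share of 0.333. These markers were measured on the same arrays and may vary together, so they are not separate trials of that chance. The count of called falls was 13 without either quiescent array, 1 without 4-week replicate 1 and 0 without any other single array. Hepatocyte markers gave 0 called falls of 24 with a median of -1.19 (0 up, 11 down adjusted over the list alone, adjusted p = 2.8e-12, adjusted p = 0.219 with an estimated correlation). Endothelial markers gave 0 of 24 with a median of -0.64 (0 up, 1 down adjusted over the list alone, adjusted p = 8.51e-08, adjusted p = 0.299 with an estimated correlation). Inflammatory genes had a median of -0.58 and no called member of 25 (1 up, 11 down adjusted over the list alone, adjusted p = 2.3e-07, adjusted p = 0.209 with an estimated correlation), with Tnf (-1.57 ± 0.29), Ccl3 (-1.56 ± 0.32) and Ccl4 (-1.45 ± 0.26) nearest the threshold. YAP/TAZ target genes had a median of 0.17 (4 up, 0 down adjusted over the list alone, adjusted p = 0.00125, adjusted p = 0.299 with an estimated correlation). Actin genes had one of 0.36 (0 up, 0 down adjusted over the list alone, adjusted p = 1.61e-05, adjusted p = 0.46 with an estimated correlation). Neither list had a called member. Ankrd1 stood at 1.78 ± 0.53 (adjusted p = 0.361) and Ccn2 at 0.81 ± 0.19 (adjusted p = 0.206). Hippo components (3 up, 0 down adjusted over the list alone, adjusted p = 0.00217, adjusted p = 0.173 with an estimated correlation) shifted upward as a list. Unfolded protein response genes did too (1 up, 0 down adjusted over the list alone, adjusted p = 0.000235, adjusted p = 0.236 with an estimated correlation). Activated markers (0 up, 1 down adjusted over the list alone, adjusted p = 0.475) and quiescent markers (1 up, 1 down adjusted over the list alone, adjusted p = 0.98) did not pass. Nor did collagens (0 up, 0 down adjusted over the list alone, adjusted p = 0.247), which passed without 2-week replicate 1 (adjusted p = 0.0422). Acta2 stood at 0.01 ± 0.20 and Lox at -0.39 ± 0.16.

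Culture stood above CCl4 in proliferation genes and below it in collagens and quiescent stellate cell markers. With an estimated correlation, these 3 list tests gave adjusted p = 0.208, 0.324 and 0.106. Against the mean of both CCl4 times, 2789 genes were higher in culture and 1933 lower. Without culture replicate 1 the lower count was 1268, and without culture replicate 2 the counts were 1683 and 1163. Higher genes were led by Tnfsf18 (6.76 ± 0.14), Cpe (6.24 ± 0.12), Cnn1 (5.75 ± 0.18), Sprr1a (5.67 ± 0.36), Zdhhc2 (5.63 ± 0.26), Parm1 (5.53 ± 0.14), Scel (5.11 ± 0.13), Ifi27l2b (4.95 ± 0.18) and Slco4a1 (4.72 ± 0.16) and by the receptor pseudogene Olfr1372-ps1 (4.96 ± 0.47). Lower genes were led by the dermatopontin gene Dpt (-7.92 ± 0.15), Sparcl1 (-7.28 ± 0.17), Serpina3n (-7.24 ± 0.70), Steap4 (-7.12 ± 0.12), Tgfbi (-6.14 ± 0.16), Saa3 (-6.05 ± 0.69), Fabp1 (-5.95 ± 0.24), Hamp (-5.86 ± 0.75) and Alb (-5.86 ± 0.18) and Cygb (-6.04 ± 0.14), the cytoglobin gene of stellate cells. Lrat (-4.54 ± 0.33), Reln (-3.89 ± 0.23), Pdgfrb (-1.35 ± 0.18), Col1a2 (-1.04 ± 0.18) and Col1a1 (-0.97 ± 0.23) were lower in culture. Ankrd1 (2.94 ± 0.46), Lox (1.36 ± 0.14), Acta2 (0.76 ± 0.18) and Ccn2 (0.67 ± 0.16) were higher. The dimmer Ccn2 probe set stood at 0.08 ± 0.21, and the dimmer Col1a2 probe set at -2.64 ± 0.23. Col1a1 (in 4 of the 8 fits, adjusted p 0.0517 to 0.0998), Ccn2 (in 3 of the 8 fits, adjusted p 0.0601 to 0.13) and Acta2 (without culture replicate 1, adjusted p = 0.0884 and without culture replicate 2, adjusted p = 0.0858) lost their calls with 1 array left out.

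YAP/TAZ target genes were higher in culture than after CCl4 on balance, 10 higher and 5 lower of 21 (11 up, 5 down adjusted over the list alone, adjusted p = 0.0136, adjusted p = 0.409 with an estimated correlation), though the test on ranks gave adjusted p = 0.0679. F3 (4.40 ± 0.25), Dock5 (2.47 ± 0.15), Fjx1 (2.43 ± 0.22) and Crim1 (2.31 ± 0.18) were higher, and Nt5e (-1.27 ± 0.17), Ccdc80 (-1.22 ± 0.13), Rbms3 (-0.76 ± 0.13), Myof (-0.58 ± 0.16) and Arhgef17 (-0.45 ± 0.12) lower. The lower members numbered 3 without either culture array, 2-week replicate 2 or either 4-week array. Myof (in 6 of the 8 fits, adjusted p 0.0685 to 0.156), Arhgef17 (in 5 of the 8 fits, adjusted p 0.0595 to 0.161), Mylk (without culture replicate 2, adjusted p = 0.0613) and Myh10 (without culture replicate 1, adjusted p = 0.068 and without culture replicate 2, adjusted p = 0.0525) lost their calls with 1 array left out. Hippo components did not pass as a list (11 up, 2 down adjusted over the list alone, adjusted p = 0.129), with 10 higher, such as Vgll3 (2.04 ± 0.22), Amot (1.35 ± 0.17) and Lats2 (1.16 ± 0.15), and 2 lower. Proliferation genes were higher in culture, 21 of 24 (22 up, 0 down adjusted over the list alone, adjusted p = 2.88e-15, adjusted p = 0.208 with an estimated correlation). Cholesterol biosynthesis genes were higher too, 6 of 16 (9 up, 0 down adjusted over the list alone, adjusted p = 0.000687, adjusted p = 0.414 with an estimated correlation). Actin genes gave 11 higher and 3 lower of 26 (14 up, 3 down adjusted over the list alone, adjusted p = 0.000617, adjusted p = 0.541 with an estimated correlation), with Cnn1 (5.75 ± 0.18) and Actg2 (3.67 ± 0.30) against Mylk (-1.28 ± 0.24) and Myh10 (-0.86 ± 0.18). The higher actin count was 6 or 5, and the cholesterol count 3 or 1, without culture replicate 1 or 2.

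Collagens were lower in culture than after CCl4, 12 lower and 2 higher of 23 (4 up, 12 down adjusted over the list alone, adjusted p = 2.85e-05, adjusted p = 0.324 with an estimated correlation). Col6a3 (-5.01 ± 0.26), Col14a1 (-4.61 ± 0.27), Col15a1 (-3.72 ± 0.17) and Col6a1 (-2.97 ± 0.15) were lower, and Col4a5 (1.62 ± 0.18) and Col11a1 (1.0 ± 0.15) higher. Activated markers did not pass as a list, with 4 higher and 9 lower of 23 (6 up, 9 down adjusted over the list alone, adjusted p = 0.22). Metalloproteinases gave 4 higher and 7 lower of 19 (4 up, 8 down adjusted over the list alone, adjusted p = 0.0625), with Mmp10 (3.89 ± 0.27) and Mmp13 (2.48 ± 0.18) against Mmp2 (-4.49 ± 0.21) and Mmp19 (-2.86 ± 0.15), a list that passed without quiescent replicate 1 or 2 (adjusted p = 0.0396 and 0.0378). Quiescent markers were lower, 19 of 24 with 1 higher (2 up, 19 down adjusted over the list alone, adjusted p = 7.75e-18, adjusted p = 0.106 with an estimated correlation). Immediate early genes were lower as well, 21 of 24 (0 up, 22 down adjusted over the list alone, adjusted p = 3.61e-25, adjusted p = 0.109 with an estimated correlation). Interferon genes gave 18 lower of 21 (0 up, 19 down adjusted over the list alone, adjusted p = 1.84e-14, adjusted p = 0.115 with an estimated correlation). Inflammatory genes gave 16 lower and 2 higher of 25 (2 up, 18 down adjusted over the list alone, adjusted p = 5.74e-10, adjusted p = 0.191 with an estimated correlation). Hedgehog genes gave 7 lower of 13 (0 up, 7 down adjusted over the list alone, adjusted p = 0.000153, adjusted p = 0.209 with an estimated correlation), with Gas1 (-2.0 ± 0.25) and Gli2 (-1.07 ± 0.13), and 3 without culture replicate 2. Hepatocyte markers gave 16 lower of 24 (1 up, 18 down adjusted over the list alone, adjusted p = 6.71e-13, adjusted p = 0.209 with an estimated correlation). Endothelial markers gave 19 of 24 (0 up, 20 down adjusted over the list alone, adjusted p = 3.38e-14, adjusted p = 0.209 with an estimated correlation). Macrophage markers gave 11 of 22 (0 up, 12 down adjusted over the list alone, adjusted p = 3.06e-06, adjusted p = 0.222 with an estimated correlation), a count of 7 without culture replicate 1. Portal fibroblast and mesothelial markers gave 9 lower and 4 higher of 21 (4 up, 11 down adjusted over the list alone, adjusted p = 0.00111, adjusted p = 0.209 with an estimated correlation). Lower members included Dpt (-7.92 ± 0.15), Cd34 (-3.72 ± 0.19), Mfap4 (-3.09 ± 0.16) and Wt1 (-2.98 ± 0.21). The higher ones were Mfap5 (3.41 ± 0.29), Fbln2 (2.66 ± 0.23), Krt19 (1.14 ± 0.15) and Slit2 (0.95 ± 0.23). Slit2 (in 3 of the 8 fits, adjusted p 0.0537 to 0.115) lost its call with 1 array left out.

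The overlap of culture and CCl4 was counted gene by gene. Culture and 2-week CCl4 shared 312 genes higher and 442 lower than quiescent, where independent lists would share 67.3 and 55.2. Culture and 4-week CCl4 shared 553 and 748, where independent lists would share 116 and 106. Genes called in opposite directions numbered 76 and 114, fewer than the 123 and 226 that independent lists would give. The CCl4 times shared 409 and 457, where independent lists would share 21.0 and 25.1. Between them 1 gene went opposite ways, against 46 for independent lists. Across genes, which are not independent replicates, log2 fold changes correlated at r = 0.55 for culture with 2-week, 0.59 for culture with 4-week and 0.85 for 2-week with 4-week CCl4. Unchanged groups sharing the quiescent arrays gave 0.50 in simulation. The same sign was found for 66.5% and 67.6% of all genes in culture and at 2 or 4 weeks, against 66.6% and 66.7% in simulation, and for 74.7% at both CCl4 times, against 66.7%. The covariances were 0.205, 0.256 and 0.193 against 0.0191 in simulation, differences of 0.186, 0.236 and 0.174. Simulated unchanged groups shared 0.01 to 0.03 called genes on average. That count is small by construction, since almost no gene is called in unchanged groups, so it does not gauge the overlaps. The simulation also gave each gene the same spread in every group, independent of other genes, while the quiescent pair differed most. With 2 quiescent arrays the controls could not be split, so part of the excess may come from the shared controls. Without 2-week replicate 1 or 2 or either 4-week array, culture and 2-week CCl4 shared 182, 391 or 487 genes in place of 754. Without 4-week replicate 1 or 2, culture and 4-week CCl4 shared 488 or 513 in place of 1301. The CCl4 times shared 225, 443, 418 or 445 in place of 866 without 2-week replicate 1, 2-week replicate 2, 4-week replicate 1 or 4-week replicate 2. The opposite counts fell to 32, 35 and 48 without 2-week replicate 1, 2-week replicate 2 and culture replicate 2 for the 2-week overlap, and to 40, 49 and 75 without 4-week replicate 1, 4-week replicate 2 and culture replicate 2 for the 4-week overlap.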

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

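The tests of technical explanations here were all chosen after the results were seen, while the comparisons themselves were planned. Culture and CCl4 differed from each other, by the direct test, in 4722 genes and in 22 gene lists. The changes from quiescent at 4 and at 2 weeks of CCl4 differed in 19 genes and 13 lists. None of these list calls was past the threshold with an estimated correlation (0 of 89 over the 5 comparisons).

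Over all genes, opposite calls were fewer than independent lists would give, 76 against 123 at 2 weeks and 114 against 226 at 4 weeks. Among named genes past the threshold in the direct test of culture against CCl4, 20 were called in opposite directions against quiescent cells in culture and at a CCl4 time. Log2 differences of matrix and mesenchymal genes were -7.92 for Dpt, -7.28 for Sparcl1, -5.01 for Col6a3, -4.49 for Mmp2, -3.72 for Cd34, -3.21 for Adamts4, -3.09 for Mfap4, -3.06 for Col6a2, -2.98 for Wt1, -2.15 for Eln and -1.52 for Itga9. Those of secreted and immune genes were -3.14 for Cxcl2, -2.88 for Ccl11, -2.68 for Irf7, -1.62 for Gpr65 and -0.68 for Ctss. The others were 5.63 for Zdhhc2, 5.53 for Parm1, 1.48 for Aldh1a1 and -4.76 for Sytl2. Opposite calls held in each of the 8 fits that left out 1 array for 9 of the 20, Dpt, Col6a3, Mmp2, Cd34, Mfap4, Wt1, Irf7, Zdhhc2 and Parm1. They held in 7 for Ccl11, Eln and Itga9, 6 for Gpr65 and Sytl2, 5 for Adamts4 and Col6a2, 1 for Aldh1a1 and Sparcl1, and 0 for Ctss and Cxcl2. Aldh1a1 lost its culture call in 7 of the 8 (adjusted p 0.0578 to 0.201) and its 2-week call without 2-week replicate 1 (0.0756). Without 4-week replicate 2, the 4-week calls of Ccl11 (0.0886) and Itga9 (0.0604) were lost, and without 4-week replicate 1 that of Wt1 (0.0593). Ctss lost its 2-week call without quiescent replicate 1 (0.0607), 2-week replicate 1 (0.0734) or 2-week replicate 2 (0.077), and its culture call in each of the other 5 fits. Of 17824 probe sets without a single gene name, 1301 passed in culture, 86 at 2 weeks and 344 at 4 weeks of CCl4 against quiescent, and 1333 in culture against CCl4.

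Activated stellate cell markers were higher after CCl4, 16 of 23 at 2 weeks and 17 at 4 weeks, with medians of 1.58 and 1.46 (list adjusted p = 0.106 and 0.109 with an estimated correlation). A loss of RNA from other cells would raise every stellate transcript alike, but quiescent stellate markers had medians of -0.76 and -0.70, which argues against it as the only cause. Because quiescent markers may fall for another reason at the same time, this test cannot exclude that such a loss added to the rises. Quiescent replicate 1, the array with the highest hepatocyte markers, did not set the calls alone, since 15 of the 16 and 15 of the 17 stayed called without it. The fit without it lacked the spread of the quiescent pair, which favours keeping calls. The mean change of activated markers was 1.79 and 1.71 there, and 2.22 and 2.14 without quiescent replicate 2. Portal fibroblast and mesothelial markers averaged 5.94 and 5.99 in quiescent arrays, 6.52 and 6.58 at 2 weeks, and 6.4 and 6.38 at 4 weeks. Medians changed little (5.22 and 5.55, 5.3 and 5.39, 5.2 and 5.12). A larger share of such cells was not tested as a cause. CCl4 and its duration, which the design names, stay open and untested as causes.

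Macrophage markers were lower at 4 than at 2 weeks of CCl4, with a median of -1.20 (SD 0.63) over the 21 above the level of receptor genes (list adjusted p = 0.106 with an estimated correlation). A lower share of every other cell type would lower their markers alike, but monocyte and neutrophil markers had a median of -0.25 (SD 0.68, 14 members), which argues against an equal fall though not against an unequal one. Medians of the members above that level were -1.36 for hepatocytes, -0.64 for endothelial cells, -0.33 for cholangiocytes (8 of 13, -0.14 over all) and -0.28 for lymphocytes (6 of 20, 0.01 over all), and the monocyte and neutrophil list of 17 passed downward (mean -0.43, adjusted p = 0.032, adjusted p = 0.607 with an estimated correlation, 0.376 without 2-week replicate 2 and 0.19 without 4-week replicate 1), so lower shares of macrophages, hepatocytes and endothelial cells, by differing amounts, may account for the difference. No single CCl4 array made it, since 22 of 22 markers had both 2-week arrays above both 4-week arrays. The time on CCl4 stays open, and no sort or gate is named in the labels.

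Immediate early genes were lower in culture, 21 of 24 (list adjusted p = 0.115 with an estimated correlation). RNA of hepatocytes, endothelial cells and macrophages may have carried them, but at 4 weeks, when the medians of those lists fell by at least 1.39, the list stood at -0.18, which argues against it. Release of the cells from the liver may induce these genes in every unseeded preparation, and the 2-week list stood at -0.06 against quiescent cells, both unseeded. Release and culture cannot be told apart here, because every unseeded group was freshly released and the cultured group was not. Culture itself, the serum of its medium and the 2.5 mM valproic acid of the shared protocol stay open and untested.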

How the results depend on the processing

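The alternatives here were all planned before any result was seen. Of the list tests under alternatives, 2570 kept direction and side of the threshold, 152 lost the call, 32 gained it and 1 turned. Of the values of named genes, 12457 kept both, 600 lost the call, 73 gained it and 0 turned. The list that turned was monocyte and neutrophil markers at 4 weeks of CCl4, at -0.74 (adjusted p = 0.00489) without quiescent replicate 2 and 0.31 without quiescent replicate 1, and the cause was not tested. For signal over background, genes under the receptor genes' 95th percentile of 4.76 log2 units are limited most. The replicate block gave 2 and 7 genes between the CCl4 times, and same-numbered arrays did not deviate together (r from -0.04 to 0.07), so replicates were not treated as pairs.

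Counts are given as higher, then lower, and for genes changed the same way, then opposite ways, in culture and 2-week, culture and 4-week, and both CCl4 times. At an adjusted p under 0.01, which calls fewer genes by construction, they were 1782 and 1454 in culture, 214 and 136 at 2 weeks, 372 and 400 at 4 weeks, 0 and 0 between CCl4 times, 1697 and 1178 for culture against CCl4, and 254 and 23, 549 and 36, 296 and 0 shared. With at least a 2-fold change, which also calls fewer by construction, they were 1255 and 1314, 309 and 296, 410 and 542, 936 and 872 (culture against CCl4), and 422 and 39, 649 and 43, 501 and 0 shared. With all probe sets they were 276 and 165 at 2 weeks, 612 lower at 4 weeks, 0 and 0 between CCl4 times, and 317 and 29, 62 opposite for culture and 4 weeks, 379 and 0 shared. In fits of only the groups compared, with fewer arrays, they were 227 and 145, 552 and 653, 14 and 68 between CCl4 times, and 266 and 27, 810 and 59, 330 and 0 shared. Between CCl4 times, quantile normalization gave 24 lower and array weights 26. The gene that went opposite ways at the CCl4 times became 0 with array weights, the intensity trend and the replicate block. Except where construction is named, the cause was not tested.

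With 1 array left out, which leaves its group 1 array, counts ran from 190 to 633 and 70 to 797 at 2 weeks, 317 to 912 and 335 to 1201 at 4 weeks, 0 to 15 and 0 to 70 between CCl4 times and 1683 to 3007 and 1163 to 2218 for culture against CCl4. Shared counts ran from 182 to 1094 and 32 to 64, 488 to 1555 and 40 to 97, and 225 to 1208 with 0 opposite. The mean of YAP/TAZ target genes ran from 0.09 to 0.36 at 2 weeks, and its list test passed without quiescent replicate 2. With an estimated correlation the list lost its call at 1.13 in culture, 0.48 at 4 weeks, 0.25 between CCl4 times and 0.78 for culture against CCl4, and on ranks at 0.78 for the last.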

Other observations

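Oxidative phosphorylation genes had a median of 0.13 at 4 weeks, 0 of 22 called higher (0 up, 0 down adjusted over the list alone, adjusted p = 0.0352, adjusted p = 0.468 with an estimated correlation), and the list call was lost without quiescent replicate 1 (adjusted p = 0.173) or 4-week replicate 2 (adjusted p = 0.0771). Cholesterol biosynthesis had a median of 0.20 and 0 called members of 16 (0 up, 0 down adjusted over the list alone, adjusted p = 0.351), with 2 rises without quiescent replicate 1. The cholesterol list passed without quiescent replicate 1 (mean 0.52, adjusted p = 0.00508) or 4-week replicate 1 (mean 0.49, adjusted p = 0.013). TGF-beta genes gave 5 rises and 4 falls of 23 at 4 weeks (7 up, 4 down adjusted over the list alone, adjusted p = 0.155), the falls numbering 0 without either 4-week array, and the list passed without quiescent replicate 2 (mean 0.50, adjusted p = 0.0432). Hedgehog genes gave 3 rises and 2 falls of 13 (3 up, 2 down adjusted over the list alone, adjusted p = 0.21). Retinoid genes gave 1 rise and 4 falls of 23 (1 up, 4 down adjusted over the list alone, adjusted p = 0.0917), and lipid genes 2 falls (0 up, 2 down adjusted over the list alone, adjusted p = 0.294).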
